A study of Serratia sp. ZM with 2 samples.

How the data were processed

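RNA-seq was run on 2 cultures of Serratia sp. ZM, a bacterium of an enterobacterial genus, grown for 10 hours with ammonium sulfate as the nitrogen source. Per the labels, one culture received 2 mM and the other 10 mM of the salt, total RNA was taken with Trizol, and libraries followed an Illumina protocol. There was 1 library per condition. The libraries are called LN and HN after their titles. The title and the growth condition of LN give low nitrogen and those of HN give high nitrogen, but the source name of each library gives the opposite condition. Groups were taken from the growth condition. Every direction reported here is therefore a direction between the library labelled LN and the library labelled HN, and would turn if the source names were right.

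Each deposited table lists, per gene identifier, a read count headed as unique reads, a gene length, the percent of the length covered and an RPKM value, that is, reads per kilobase of gene and per 1000000 reads. The counts are whole numbers as the authors deposited them and add up exactly to the library total in the header of each table. Genes are listed from 1 read upwards, so a gene listed in only 1 table was taken as having 0 reads in the other. The authors' RPKM values equal reads divided by length and by that library total, with a relative difference of at most 7.09e-09. All lengths are multiples of 3, so they are coding lengths without untranslated regions, from 93 to 10017 bases. Genes with 1 read had a median of 90 bases covered, which gives the length of a read. The covered share of 3 genes in HN slightly exceeded 100%, with a highest value of 100.33%. The aligner, the counting tool, the genome build, the annotation and the handling of strand are not given in the sources used here. Unique counting can take reads from genes with near-identical copies, and without a stated strand, reads of overlapping genes cannot be told apart.

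The deposited tables do not pair the identifiers with gene names or products, and no genome or annotation was used here. The 26 gene lists fixed before the data were examined (nitrogen regulation, ammonium assimilation, ribosomal proteins and others) hold gene symbols, 0 of which occur among the identifiers, so no list was evaluated. The rule fixed for this case names the 2 identifiers with the highest and the 2 with the lowest log2 ratio.

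For each gene the log2 ratio was log2((LN RPKM + 1) / (HN RPKM + 1)). The pseudocount of 1 RPKM understates changes of genes with low values. Genes with a mean of at least 10 RPKM over the 2 libraries were compared, and a difference of at least 2-fold on this scale was counted. With 1 library per condition there is no replicate spread, no test between conditions was possible, and no p-value is given. An exact 95% interval of each ratio of read counts (Clopper-Pearson, conditional on the sum of both libraries) was computed. Such intervals, and the limit of 3 reads that a count of 0 allows, cover counting error only. PCR reads without molecular identifiers are not independent molecules. The differences expected from counting error alone were simulated by splitting the reads of each gene at random between the libraries in 1000 draws.

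Genes were also sorted by the number in their identifiers, after the data had been seen. A run was defined as at least 4 neighbouring identifiers that all passed the filter and all differed at least 2-fold in the same direction. Neighbours are identifiers next to each other among those listed in either table. The numbers rise in steps of 5, except for 44 identifiers at the end of the numbering, whose numbers are no multiple of 5. Of the 4353 steps between listed identifiers, 150 were larger than 5 and were taken to skip numbers that neither table lists. Skipped numbers were passed over. For comparison, the log2 ratios were shuffled 10000 times among genes of the same class out of 10 abundance classes. That the numbering follows the order of genes in the genome is an assumption.

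The calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. R 4.3.3 with edgeR 4.0.16 gave the TMM factors of 1 alternative scaling and no test. The procedure was tested on simulated counts for 3684 genes at the depth of these libraries. The simulation held counting error only, which is the error that the intervals assume. Differences between cultures or library preparations were not simulated. Of the exact intervals, 95.8% held the true ratio, 0.0861% of unchanged genes were counted as 2-fold different, and 100% of genes changed 4-fold and 42% of genes changed exactly 2-fold were counted in the right direction. Alternatives fixed before the data were examined were other pseudocounts, filters, scalings and fold limits, and a requirement that the interval exclude no change.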

Results

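The data set compared the gene expression of Serratia sp. ZM at 2 concentrations of ammonium sulfate, a salt that supplies nitrogen as ammonium. The library labelled LN came from a culture with 2 mM and the library labelled HN from a culture with 10 mM, both after 10 hours, with 1 library each. The source names of the libraries give the opposite assignment, so each direction is stated between LN and HN as titled. LN held 7074592 uniquely counted reads in 4345 genes and HN held 7672549 in 4340 genes. Together the libraries listed 4354 genes, of which 4331 had reads in both. The median listed gene had 399 reads in LN and 406 reads in HN. At least 90% of the length was covered in 86.5% of the genes listed in LN and in 86.2% of those listed in HN.

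The question of the series was which genes differ in expression between low and high nitrogen supply. Of 3684 genes with a mean of at least 10 RPKM, 539 (14.6%) were at least 2-fold higher in LN and 491 (13.3%) were at least 2-fold lower. The remaining 2654 genes (72.0%) lay within 2-fold. At least 4-fold differences were found in 145 genes that were higher and 158 that were lower in LN. At least 16-fold differences were less evenly divided, with 56 genes higher and 19 lower. Of the genes that differed at least 100-fold, 7 were higher and 1 was lower in LN. The median gene was 0.17 higher in LN on the log2 scale, and relative to this median 398 genes were higher and 604 lower, so that the share of higher genes among those that differed was 52.3% as deposited and 39.7% after centring.

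Counting error was small against these differences. The median gene past the filter had 584 reads in LN and 579 in HN, and the exact 95% intervals had a median half-width of 0.18 on the log2 scale. The interval excluded equal expression in all 1030 genes that differed at least 2-fold and in 3021 (82.0%) of all genes past the filter. Splitting the reads at random between the libraries gave a median of 1 and at most 5 genes with a 2-fold difference in 1000 draws. These intervals compare the libraries and not the conditions. Without replicate cultures, differences between individual cultures or library preparations cannot be separated from the nitrogen supply.

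The gene with the highest ratio was SERRSCBI_15770, with 6807 RPKM (53888 reads) in LN and 4.78 RPKM (41 reads) in HN. It was 1425-fold higher in LN (exact 95% interval 1051 to 1987), with a log2 ratio of 10.20 including the pseudocount. It ranked 20 among all genes by RPKM in LN and 3954 in HN. SERRSCBI_15375 followed with 4667 RPKM in LN and 5.92 RPKM in HN, a 788-fold difference (583 to 1093). The lowest ratio belonged to SERRSCBI_17620, with 5.95 RPKM (26 reads) in LN and 1914 RPKM (9077 reads) in HN. It was 322-fold higher in HN (220 to 493), a log2 ratio of -8.11. SERRSCBI_17105 had 5.75 RPKM in LN and 491 RPKM in HN, an 85.4-fold difference (64.7 to 115). All 4 genes were covered over at least 89.11% of their coding length in both libraries. The tables do not pair these identifiers with gene names, so their products are not given here.

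**Figure D1:**
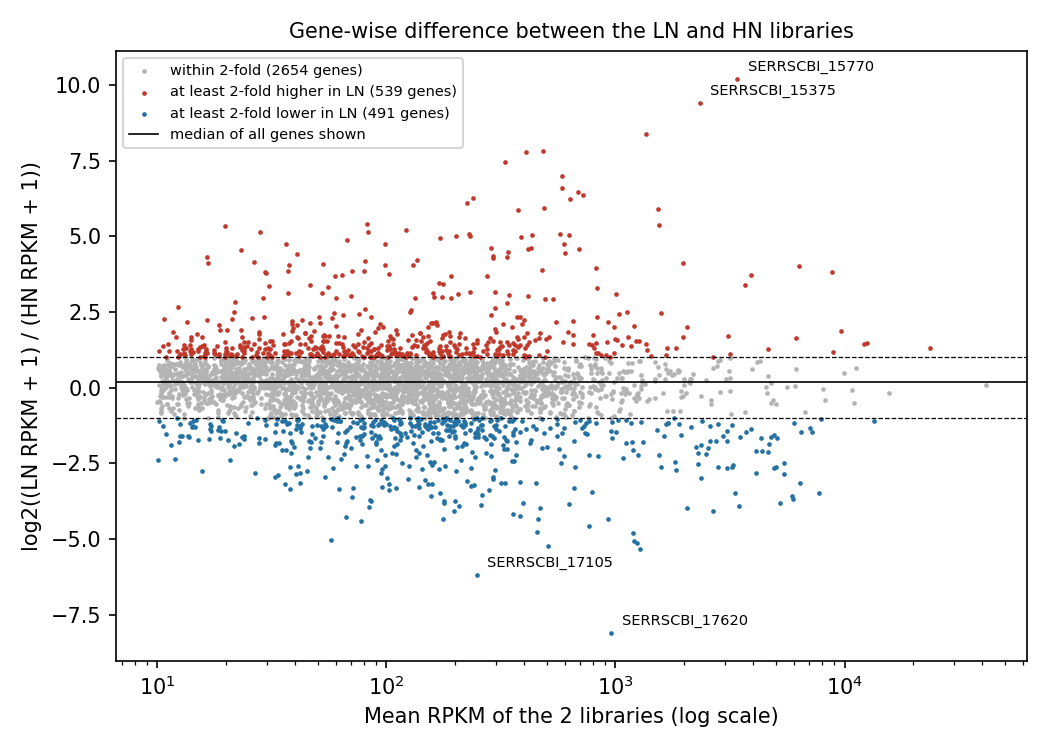
The log2 ratio of LN to HN (vertical axis, RPKM plus 1) is plotted against the mean RPKM of both libraries (horizontal axis, log scale) for the 3684 genes past the filter, 1 point per gene. Dashed lines mark 2-fold differences, the solid line marks the median of 0.17, and the 539 higher and 491 lower genes are coloured, with the 2 highest and 2 lowest ratios labelled.

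The genes that differed held a large part of each library. Genes at least 2-fold higher in LN took 30.2% of the reads in LN and 7.61% in HN, and genes at least 2-fold lower took 8.55% in LN and 33.0% in HN. Genes within 2-fold took 60.9% and 59.1%. Of the 20 genes with the highest RPKM in each library, 8 were shared. Among the 20 in LN, 10 were at least 2-fold higher in LN, and among the 20 in HN, 13 were at least 2-fold lower in LN. Of all genes past the filter, 14.6% were higher and 13.3% lower. Part of the excess follows from ranking genes by the library in which they were high, and the read shares follow in part from the calls. Across the genes past the filter, which are not independent replicates, the RPKM values of the libraries had a Spearman correlation of 0.81. The same gene had the most reads in both libraries, with 234159 reads (3.31%) in LN and 111839 reads (1.46%) in HN.

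Among weakly expressed genes, more were higher than lower in LN with the values as deposited. The genes past the filter were ranked by mean RPKM and divided into 5 classes of equal size. In the highest class (at least 322 RPKM), 37.2% differed at least 2-fold, with 126 higher and 148 lower in LN. In the lowest class (10.0 to 31.6 RPKM), 21.7% differed, with 111 higher and 49 lower. Part of the larger share in the highest class follows from the ranking, since a gene abundant in only 1 library has a high mean. With classes by the mean of log2(RPKM + 1), chosen after the data had been seen, the shares were 30.4% in the highest and 25.6% in the lowest class. By mean RPKM, the median log2 ratio was 0.34 in the lowest class and 0.04 in the highest, against 0.17 over all genes past the filter. When ratios are centred on that median, the sign in the highest class turns and the shift in the lowest class becomes smaller. The counts per class were not taken after centring.

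Genes with neighbouring identifiers differed together. The log2 ratios of genes 1 place apart in the numbering correlated across 3371 pairs with a Pearson r of 0.59, against at most 0.07 in 10000 shuffles within abundance classes. The correlation was 0.24 at 3 places and 0.07 at 10 places. There were 60 runs of at least 4 neighbouring genes that all differed at least 2-fold in the same direction, 28 higher and 32 lower in LN, and they held 321 genes, or 31.2% of all that differed. The shuffles gave 2.32 runs on average and at most 9.

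**Figure D2:**
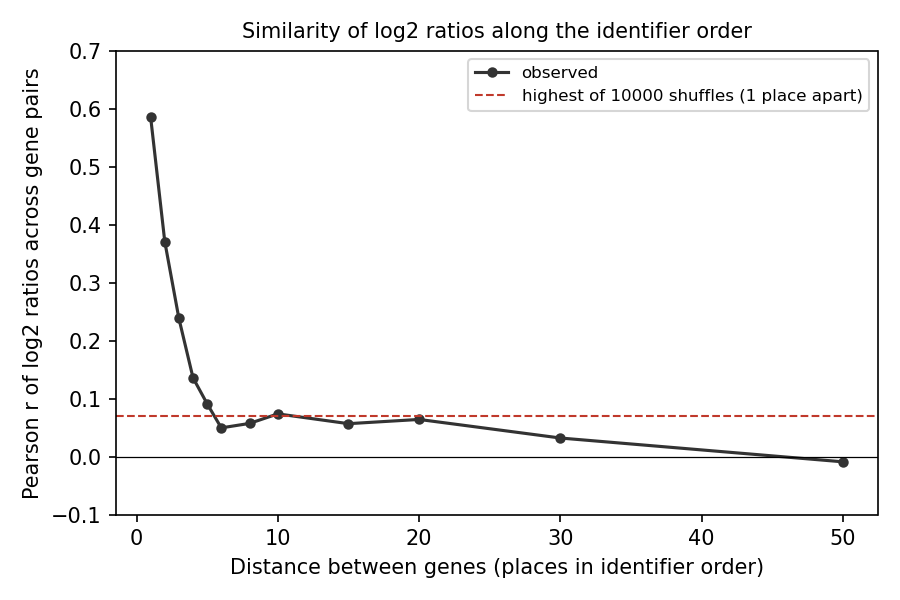
The Pearson correlation of log2 ratios across pairs of genes (vertical axis) is plotted against their distance in the identifier numbering (horizontal axis, places), with a dashed line at the highest value of 10000 shuffles for genes 1 place apart. The correlation falls from 0.59 at 1 place to 0.09 at 5 places.

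The run with the highest median ratio held 7 genes, among them SERRSCBI_15770, and had a median log2 ratio of 7.46. Its genes had 65.3 to 6807 RPKM in LN and 2.68 to 27.6 RPKM in HN, and together they took 1.12% of the reads in LN and 0.00444% in HN. Numbers listed in neither table lie before its last gene, and without that gene the 6 others had a median of 7.62. SERRSCBI_15375 lay in another run of 4 genes, which had a median log2 ratio of 5.13. The longest run higher in LN had 10 genes with a median log2 ratio of 4.37 (1.12 to 5.34), at 32.2 to 90.5 RPKM in LN and 0 to 41.0 RPKM in HN. Its median of 1.33 RPKM in HN lies near the pseudocount of 1 RPKM, so the size of these ratios depends on the pseudocount.

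The run with the lowest median ratio held 4 genes with a median log2 ratio of -3.80, at 23.2 to 32.5 RPKM in LN and 289 to 989 RPKM in HN. Unlisted numbers lie after its first gene, and if runs end at such numbers, it is no run and the lowest median is -3.33, in another run of 4 genes. The longest run lower in LN held 10 genes with a median log2 ratio of -2.11, at 466 to 1414 RPKM in LN and 1506 to 8679 RPKM in HN. A run of 9 genes with a median log2 ratio of -1.87 preceded it, separated by 1 gene with a log2 ratio of -0.93. These 19 genes took 0.951% of the reads in LN and 3.83% in HN. The run with the most reads in HN held 5 genes, which took 2.57% of the reads in HN and 0.455% in LN, with a median log2 ratio of -2.85. Neither SERRSCBI_17620 nor SERRSCBI_17105 lay in a run.

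**Figure D3:**
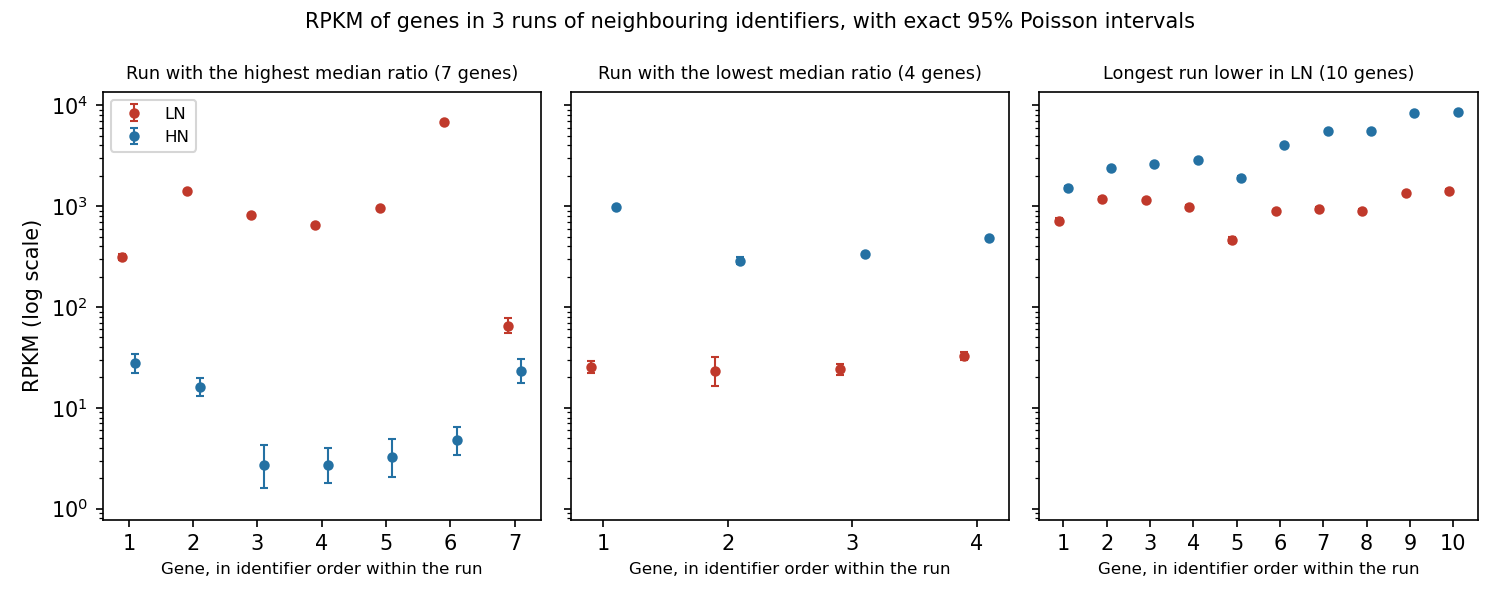
RPKM (vertical axis, log scale) is plotted for each gene of 3 runs, in identifier order (horizontal axis), in LN (red) and HN (blue), with exact 95% Poisson intervals that cover counting error only. All genes of the first run were higher in LN, by median 7.46 on the log2 scale, and all genes of the other runs were lower in LN, by median log2 ratios of -3.80 and -2.11.

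The libraries differed little in which genes had any reads. LN listed 14 genes that HN did not, and HN listed 9 that LN did not. Of these 23 genes, 22 had at most 11 reads. The exception, picked out after its values were seen, was a gene of 714 bases with 200 reads in LN (39.6 RPKM, 98.88% of its length covered) and 0 reads in HN. A count of 0 allows up to 3 reads or 0.548 RPKM there, and 39.6 RPKM is 72.3 times that limit with the 200 reads taken as exact. The exact 95% interval of the ratio, which also covers the counting error of the 200 reads, starts at 58.3-fold higher in LN.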

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

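The covered share of each gene was not used in the comparison between the libraries, and the limits and tests on it were chosen after it had been seen, except for the simulated placement of reads, whose prediction was written before its result.

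Of 3068 genes with at least 100 reads in each library, 43 (1.40%) had less than 85% of their length covered in both libraries. Their covered share had a median of 75.2% in LN and 76.2% in HN. The most deeply read of them, a gene of 1068 bases, had 10708 reads in LN and 19758 reads in HN and was covered over 71.16% and 71.35% of its length. Shallow sampling by independent reads is argued against, because placing the same numbers of 90-base reads at random gave 0 such genes in each of 20 simulations. The genes with the most reads in both libraries, among them the gene of 1068 bases, were left out of the simulations. Uneven placement along a gene and PCR copies were not simulated. In 36 of the 43 genes the covered share differed by at most 5 percentage points between the libraries. That value would follow both from sequence of strain ZM differing from the reference used for counting and from repeated sequence left out by unique counting, and these could not be told apart without the reads or the genome. The design gives no biological explanation by group. In those 36 genes, a part that takes no reads would lower the RPKM in both libraries about alike, which is not shown for the rest. Of the 43 genes, 5 were among those that differed at least 2-fold.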

How the results depend on the processing

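Counts of genes that differed at least 2-fold moved by less than 1.5 times under each planned pseudocount, filter and scaling: 772 to 1123 genes in total, with 375 to 605 higher and 397 to 604 lower in LN, against 539 and 491. The 4-fold limit gave 303 genes by its own construction, 145 higher and 158 lower. Requiring the exact interval to exclude no change removed 0 of the 1030 genes. The split between higher and lower genes depended on the scaling. The share of higher genes was 52.3% as deposited, 58.8% after rescaling to TPM, 55.5% with the 20 most abundant genes left out of the totals, 39.7% after centring on the median and 39.8% after TMM scaling. Of the 1030 genes, 889 were counted in the same direction after centring. The log2 ratios of the 4 named identifiers kept their sign in all 32 values under alternatives, and 4 values, all at a pseudocount of 5 RPKM, moved beyond counting error. The kept sign follows from picking the most extreme ratios, and a change of filter leaves a ratio as it is. Settings for neighbouring identifiers were added after the data had been seen: the correlation was 0.56 to 0.65 (0.65 at a mean of at least 50 RPKM), and the 60 runs became 44 to 66 under other pseudocounts, filters and scalings, 113 with a minimum of 3 genes, 24 with a minimum of 6 and 59 when runs end at skipped numbers. With 1 library per condition no replicate could be left out, and the planned medians of the 26 fixed gene lists were not run because the identifiers carry no names. The exact intervals of genes with reads in both libraries had a median half-width of 0.79 on the log2 scale under 10 RPKM and 0.18 above, and 107 genes past the filter had under 100 reads in both libraries together.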

Other observations

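Of the tests in this part, those on the correlation 10 places apart and on a single shared factor were chosen after the result was seen. The patterns themselves were all noticed in these data.

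Genes under the filter were shifted towards LN as well, with the values as deposited. Of 670 genes with a mean under 10 RPKM, 463 had a higher RPKM in LN, and their pooled reads per library total were 0.32 higher in LN on the log2 scale. The gene with 200 reads in LN and 0 in HN belonged to the run of 10 genes higher in LN, whose other 9 genes had a median log2 ratio of 4.33, and their pooled ratio would give 10.5 reads for it in HN. That pooled ratio rests on 235 reads in HN, unevenly spread at 4 to 83 per gene.

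Genes with neighbouring identifiers differed together, with a correlation of 0.59 between log2 ratios 1 place apart. Similar abundance of neighbouring genes is argued against, because shuffles within abundance classes gave at most 0.069. Reads spanning neighbouring genes are argued against as the whole cause, because pairs in which both genes had at least 1000 bases, 458 in all, gave a correlation of 0.62 (bootstrap 95% interval 0.51 to 0.71). The interval takes the pairs as independent, although some share a gene, and may be too narrow. The correlation fell to 0.050 at 6 places, a drop that transcripts shared by neighbouring genes, as in bacterial operons, would give. It fell no further up to 20 places, with 0.074 at 10 places and 0.064 at 20 places. The source of this remainder was not tested. Separate transcripts of nearby genes under one regulator stay open and were not tested.

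The numbers of 44 identifiers, all at the end of the numbering, are no multiple of 5, unlike all others. Of these genes, 38 had a higher RPKM in LN, with a median log2 ratio of 0.65, and of the 24 that passed the filter 7 were at least 2-fold higher and 0 at least 2-fold lower, against 14.6% and 13.3% of all genes past the filter. Those with at least 100 reads in each library were part-covered in 8 of 17 cases (47.1%), against 35 of 3051 (1.15%) of the other genes. Among 10000 lists matched on mean expression, with a median of 0.27 and a highest value of 0.67, the group lay at percentile 99.97. The lists draw scattered genes, whereas the group holds neighbouring identifiers, whose ratios correlate, so the lists spread too little. The lists alone therefore cannot decide whether a shift of weakly expressed genes accounts for the group. Its 24 genes past the filter had a median log2 ratio of 0.90, and 21 of them were higher in LN. The lowest abundance class of all genes past the filter had a median of 0.34. The group's shift was thus not confined to genes under the filter and was larger than that of weakly expressed genes at large. A single factor shared by all of these genes, such as copy number, would alone give them 1 common ratio. The 17 well-read genes had ratios of LN to HN from 0.518 to 2.79 (median 1.89). Such a factor thus stays open only beside differences of single genes. The test of it compared the spread of the group's log2 ratios. Their SD of 0.60 lay at percentile 2.82 of the 71 windows of other identifiers with as many genes higher in LN. These windows overlap and hold 7 separate stretches, too few to decide. Earlier forms of this test, on exact intervals and on the lower quartile, were set aside because their outcome followed from counting depth or from how the group was noticed. The correlation between neighbouring genes stays open too, because 158 of 4267 windows of 44 other neighbouring identifiers had as high a median, with a highest value of 1.02. The group lay at percentile 96.3 of these windows. They overlap as well, and how many separate stretches the 158 hold was not counted.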
